A study of Homo sapiens with 14 samples.

How the data were processed

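RNA was measured by sequencing in 14 human primary T-cell lymphomas. The labels name 8 of them anaplastic large cell lymphoma (ALCL) and 6 peripheral T-cell lymphoma (PTCL). Samples were grouped by that label alone and numbered within each group, so a number names a sample and pairs it with no other. The labels do not state that each sample came from a separate donor, and p-values then measure the spread between these samples, part of which may be technical. Per the labels' protocols, total RNA was used and 2 Illumina library protocols are named for every sample, with no record of which sample received which. No sequencing batch could therefore be tested.

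The deposited table gave FPKM, fragments per kilobase of transcript and 1000000 mapped fragments, which the authors computed before deposit. CASAVA 1.8, TopHat2, Cufflinks and the hg19 genome build are named per the submitters' processing notes, without their order or settings. The annotation used for counting, strand handling and scaling between samples are not given in the sources used here. The table held 14417 loci with their hg19 positions, and 628 of them named several gene symbols at once. In 22 loci a spreadsheet had turned the symbol into a date, and these were tested without a name. XIST and Y-linked genes, 18 loci, were left out of every test. Start positions are given counted from 1, and each span is that of the locus in the table, which can be wider than the gene.

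FPKM values are not counts, so no count model was used. Values were analysed as log2(FPKM + 1), with no further scaling, and every fold change is on that scale, which understates changes of low genes. Loci with at least 1 FPKM in at least 6 samples were tested, 11248 in all. A 2-group linear model with moderated variances and a mean trend was fitted in limma 3.58.1 under R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Single genes, list means and distances between samples were also tested by exact permutation over all 3003 splits of the 14 samples into 6 and 8. Distance was 1 minus Pearson r. The test of separation was one-sided for larger distance between groups. The test of nearest samples was one-sided for more of them in the same group, and the other exact tests were two-sided.

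Gene lists were tested with camera in limma at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. The 36 lists held 418 symbols, of which 348 had a locus of their own, and a list needed at least 3 tested members, which 31 had. The lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined. By that rule 16 genes were always named, and so were up to 8 passing genes per direction or, if none passed, the 5 with the smallest p in each direction. For each list the rule names up to 2 passing members per direction or, if none passed, 1 or 2 members with the smallest p. Immunoglobulin and receptor segments, genes often absent from a germline and locus-only names were excluded from the ranking by p. FUT9, among the 16 genes, had no locus here and is not analysed here.

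Alternatives were pseudocounts of 0.1 and 0.5, no filter and a stricter filter of 5 FPKM, rescaling to a fixed total (TPM), median-of-ratios scaling and quantile normalization. Others were fits without trend, with robust moderation, with estimated sample weights and with a covariate for non-T cells, an exact rank test, rank correlation, the 1000 most variable genes, and leaving out each sample in turn. Chosen after seeing the data were the fits on 12 samples without ALCL 1 and ALCL 2, the fits on 11 samples also without PTCL 6, the counting of joint loci as list members, leaving single samples out of the non-T-cell score and of the ratio of HAND1 to NSMCE2, and the exact permutation of list means.

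Depth is not stated. Relative depth was estimated from low values: the 2nd percentile of non-zero FPKM times transcript length in kilobases, over 864 genes with 1 annotated transcript longer than 800 nt. The estimate holds only if FPKM was scaled by each library's own mapped fragments, which is not given. ALCL 1 and ALCL 2 are called shallow on this estimate. Lengths came from GENCODE release names on another genome build, and none of its coordinates were used. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The gene test was tried on simulated data with the real means of the 11248 loci and 200 changed genes in each of 20 runs. Noise was normal, with the moderated variance of each locus, and equal in all samples. It called 15.1% of genes changed by 1 on the log2 scale, 77.1% of those changed by 2 and 95.3% of those changed by 3. False calls made up 5.57% of all calls. Genes were simulated as independent, so this says nothing on correlation within lists. Shallow libraries were not simulated, and the adjustment is less strict where 200 genes change than where few do. These percentages may therefore overstate the power in the real samples.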

Results

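RNA levels were compared between 8 ALCL and 6 PTCL samples, both of them cancers of mature T cells. The series title asks where peripheral T-cell lymphomas with the surface markers CD30 and CD15 stand relative to ALCL without ALK. The labels do not say which of these samples carried either marker. FPKM sums ranged from 369166 to 4499090 per sample, while upper quartiles lay between 16.9 and 19.7. ALCL 1 and ALCL 2 stood apart: 26.1% and 31.0% of loci were listed at 0, against 2.50% to 7.72% in the other 12 samples. If FPKM was scaled by each library's own mapped fragments, their lowest non-zero values imply 8.85% and 8.25% of the fragments of the deepest sample. The others lay at 24.5% to 100%. Their 10 highest loci held 64.2% and 90.002% of the FPKM sum, against 13.3% to 23.0% elsewhere. The absolute depth and the scaling between samples are unknown, so shallow is here an estimate.

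**Figure D1:**
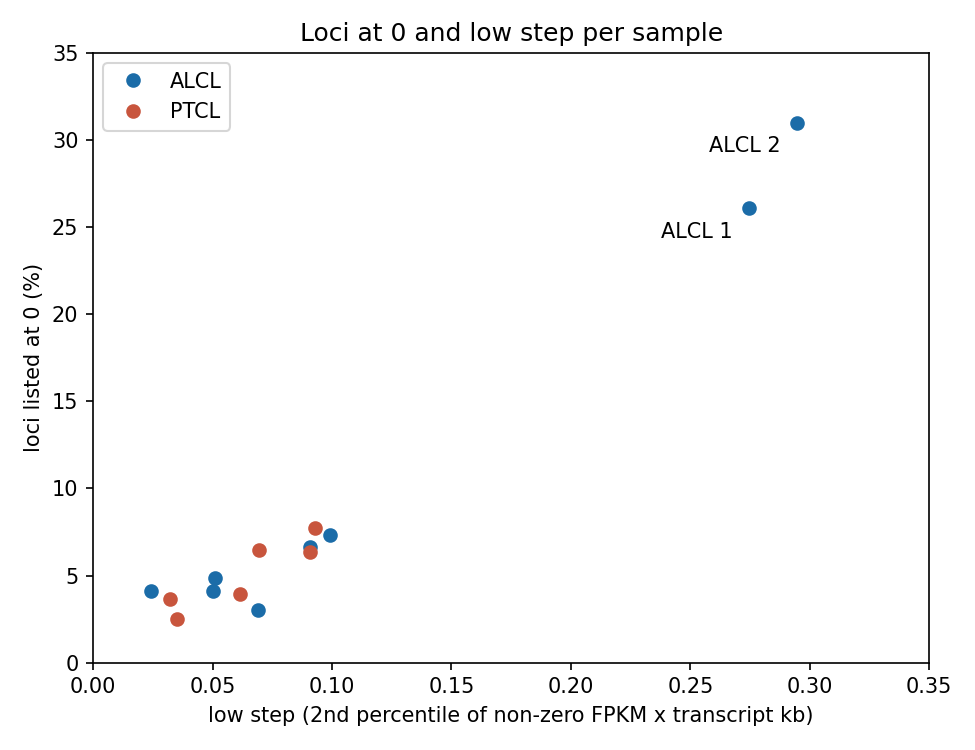
Each point is 1 sample, with the percentage of loci listed at 0 on the y axis and, on the x axis, the 2nd percentile of non-zero FPKM times transcript kilobases. The latter is higher at lower depth if FPKM was scaled by each library's own mapped fragments. ALCL 1 and ALCL 2 lie at 0.275 and 0.295 on the x axis, and the other 12 samples lie between 0.0243 and 0.0993.

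The genes behind the 2 markers of the title had levels that overlapped between the groups. TNFRSF8 (hg19 chromosome 1, 12123434 to 12204264), which encodes CD30, had 43.2 ± 25.9 FPKM in PTCL (SD, n = 6) and 52.1 ± 30.1 FPKM in ALCL (SD, n = 8). Its difference, PTCL minus ALCL, was -0.21 on the log2 scale (95% interval -1.57 to 1.15, exact permutation p = 0.784). Levels ranged from 6.57 to 69.1 FPKM in PTCL and from 5.42 to 86.9 FPKM in ALCL. FUT4, a fucosyltransferase that makes the CD15 sugar, shared its locus with PIWIL4 (chromosome 11, 94277017 to 94354587), so its own level could not be separated. That locus had 4.20 ± 2.32 FPKM in PTCL and 6.13 ± 3.45 FPKM in ALCL, a difference of -0.43 (95% interval -1.18 to 0.33, exact permutation p = 0.247). Both intervals include a level lower in PTCL by 1 on the log2 scale, and that of TNFRSF8 also a level higher by 1. RNA does not measure the CD15 sugar itself.

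BATF3 and TMOD1, which with TNFRSF8 form a known expression model for telling ALCL from other T-cell lymphomas, also overlapped between groups. BATF3, a transcription factor, had 34.5 ± 18.5 FPKM in PTCL and 45.9 ± 25.6 FPKM in ALCL. TMOD1, an actin-capping protein, had 18.2 ± 7.66 and 20.2 ± 15.4 FPKM, with a difference on the log2 scale of 0.38, opposite in sign to that of the means. The mean log2 value of the 3 genes was 4.73 ± 0.73 in PTCL (SD, n = 6) and 4.69 ± 1.48 in ALCL (SD, n = 8), a difference of 0.04 (exact permutation p = 0.961). ALCL 7 had a score of 1.37, with 0.315 FPKM of BATF3 and 0.0339 FPKM of TMOD1, and the difference without it was -0.43.

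**Figure D2:**
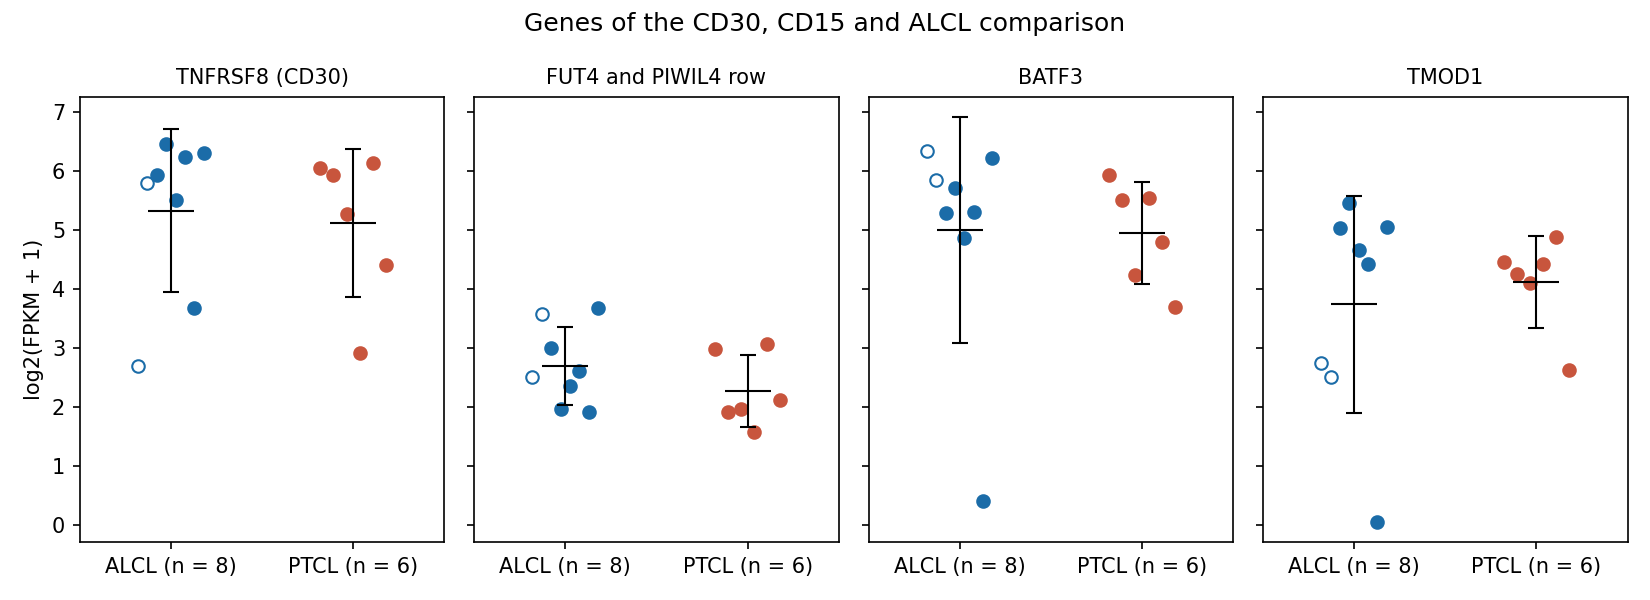
Points give log2(FPKM + 1) per sample for TNFRSF8, the locus of FUT4 and PIWIL4, BATF3 and TMOD1 in 8 ALCL and 6 PTCL samples; bars are the mean and SD, and open circles are ALCL 1 and ALCL 2. The groups overlap in all 4 panels, with differences of -0.21 for TNFRSF8 and -0.43 for the FUT4 and PIWIL4 locus.

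Among the other genes named in advance, DUSP22 and PAX5 had the smallest p-values. DUSP22, a phosphatase, had 8.77 ± 4.53 FPKM in PTCL and 3.02 ± 1.72 FPKM in ALCL, a difference of 1.29 (exact permutation p = 0.0170, adjusted p = 0.255 over the 15 genes measured). PAX5, a B-cell transcription factor, had 6.45 ± 5.12 and 1.69 ± 3.54 FPKM, a difference of 1.61 (exact permutation p = 0.04995, adjusted p = 0.375). Neither passed the correction. The cytotoxic genes GZMB and PRF1 had 47.1 ± 28.7 and 53.6 ± 53.8 FPKM in PTCL, against 29.4 ± 38.8 and 35.2 ± 61.3 FPKM in ALCL. TIA1, of cytotoxic granules, had 16.6 ± 8.12 and 16.3 ± 4.39 FPKM. ALK, the kinase whose absence defines part of ALCL, had 5.34 ± 4.05 and 4.16 ± 3.45 FPKM. TP63 had 18.7 ± 33.1 and 12.3 ± 15.7 FPKM, and MUC1, an epithelial mucin, 23.6 ± 26.8 and 30.9 ± 54.3 FPKM. The T-cell surface genes CD3E, CD4 and CD8A had 145 ± 126, 22.2 ± 19.3 and 21.7 ± 10.996 FPKM in PTCL, against 116 ± 117, 20.03 ± 14.9 and 28.8 ± 24.1 FPKM in ALCL. The differences on the log2 scale of MUC1 (1.28), CD8A (0.01) and TIA1 (-0.05) were opposite in sign to those of their means. For these genes the exact permutation p-values ran from 0.150 for GZMB to 0.988 for CD8A.

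Across all 11248 loci, no gene passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.517. At an unadjusted p under 0.05 there were 535 genes, 364 higher and 171 lower in PTCL, where chance alone would give 562. The exact rank test gave 526 genes with an unadjusted p under 0.05 and 0 after adjustment, but for any to pass, 150 loci would have to reach 0.00067, the smallest p it can give with 14 samples, so this 0 says little. The share of genes higher in PTCL at this threshold depended on the scaling: 68.0% of the 535 as deposited, 48.8% of 514 after quantile normalization and 97.3% of 847 after rescaling to TPM. The median difference of all loci was 0.10 as deposited, 0.01 after quantile normalization and 0.58 after rescaling to TPM. Without ALCL 1 and ALCL 2, an alternative chosen after seeing the data, 2 of 11049 loci passed in limma and 925 had an unadjusted p under 0.05.

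The 5 genes with the smallest p in each direction are given although none passed. Higher in PTCL were CLU, H2AFB2, KDM7A, PODXL and PIK3R5. CLU (chromosome 8, 27454434 to 27472331), a secreted chaperone, had 161 ± 188 FPKM in PTCL and 12.3 ± 8.53 FPKM in ALCL, a difference of 2.94 (SE 0.73). H2AFB2, a histone variant with near-identical copies that may share its fragments, had 5.37 ± 4.57 and 0.431 ± 0.670 FPKM. KDM7A, a histone demethylase, had 11.8 ± 5.20 and 4.13 ± 0.760 FPKM, PODXL 2.84 ± 0.627 and 0.929 ± 0.678 FPKM, and PIK3R5, a regulatory subunit of a phosphoinositide kinase, 4.52 ± 3.08 and 0.970 ± 0.781 FPKM. Lower in PTCL were ASB2, P2RY14, HIST1H3J, HAND1 and CA2. ASB2 (chromosome 14, 94400499 to 94443076), a subunit of a ubiquitin ligase, had 1.43 ± 1.68 FPKM in PTCL and 12.8 ± 7.38 FPKM in ALCL, a difference of -2.40 (SE 0.53). P2RY14, a receptor for nucleotide sugars, had 6.10 ± 3.33 and 19.7 ± 9.31 FPKM. HIST1H3J, a histone gene, had 30.5 ± 10.2 and 80.5 ± 32.7 FPKM, and CA2, a carbonic anhydrase, 7.02 ± 3.92 and 48.9 ± 50.8 FPKM. HAND1, a transcription factor of heart development, was listed at 0 in all 6 PTCL and at 0 to 69.2 FPKM in ALCL.

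Without ALCL 1 and ALCL 2, ASB2 and NSMCE2 passed in limma. ASB2 differed by -2.67 (SE 0.35, adjusted p = 0.0166 in limma) and was lower in each of the 6 PTCL than in any of the 6 remaining ALCL. The left-out ALCL 1 had 0.621 FPKM of ASB2, within the PTCL range of 0.279 to 4.78 FPKM, and ALCL 2 had 23.4 FPKM. The full separation thus rests on leaving out ALCL 1. NSMCE2 (chromosome 8, 126104083 to 126379367), a SUMO ligase of DNA repair that was named after its values were seen, had 23.2 ± 5.94 FPKM in 6 PTCL and 350 ± 210 FPKM in 6 ALCL. It differed by -3.58 (SE 0.44, adjusted p = 0.0140 in limma), against -2.67 with all 14 samples (adjusted p = 0.896 in limma). ALCL 1 and ALCL 2 had 10.03 and 45.2 FPKM of NSMCE2, the lowest of the ALCL values, so leaving them out favours a larger difference. Without PTCL 6 as well, 0 genes passed. With all 14 samples and estimated sample weights, chosen before the data were seen, 9 loci passed in limma, among them NSMCE2 (adjusted p = 0.00195), HAND1 (adjusted p = 0.00998), ASB2, P2RY14, HIST1H3J and H2AFB2.

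**Figure D3:**
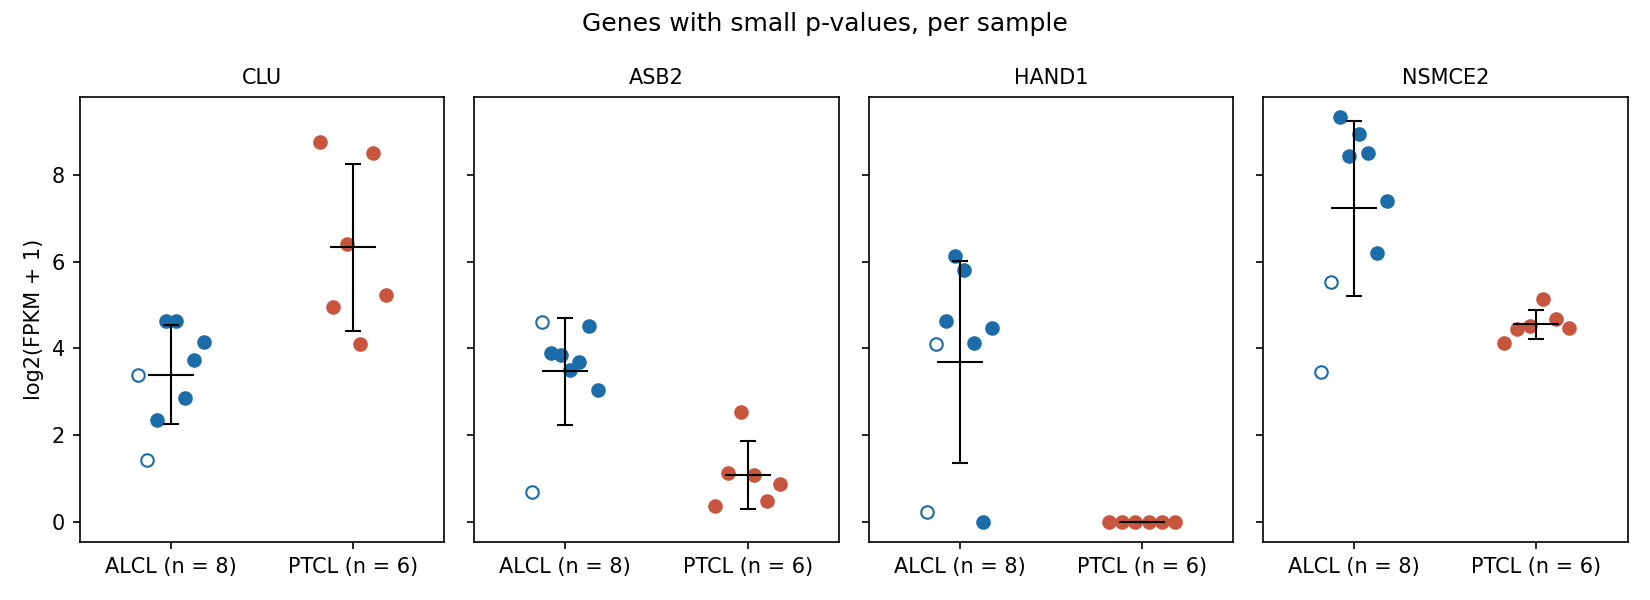
Points give log2(FPKM + 1) per sample for CLU, ASB2, HAND1 and NSMCE2 in 8 ALCL and 6 PTCL samples; bars are the mean and SD, and open circles are ALCL 1 and ALCL 2. HAND1 is listed at 0 in all 6 PTCL, and NSMCE2 spans 16.5 to 34.0 FPKM in PTCL and 10.03 to 651 FPKM in ALCL.

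Markers of several non-tumour cell types lay higher in PTCL. All 9 tested B-cell markers were higher on the log2 scale, with a median difference of 1.15 (camera adjusted p = 0.01004 in limma, adjusted p = 0.514 with an estimated correlation). The mean FPKM of BLK was lower in PTCL, 29.1 against 37.8 in ALCL, and its log2 difference was -0.03 without ALCL 1 and ALCL 2. PAX5 is given above, and CD72, a B-cell surface receptor, had 7.92 ± 2.06 FPKM in PTCL and 3.96 ± 4.30 FPKM in ALCL. All 6 plasma-cell markers were higher on the log2 scale (median 0.88, camera adjusted p = 0.0186 in limma, adjusted p = 0.466 with an estimated correlation). The mean FPKM of FCRL5 was lower in PTCL, 5.75 against 7.12 in ALCL. IGJ, the joining chain of secreted antibodies, had 86.5 ± 115 and 16.3 ± 16.7 FPKM, and XBP1, a transcription factor of secretory cells, 21.5 ± 11.04 and 11.9 ± 10.3 FPKM. All 10 macrophage markers were higher (median 0.85, camera adjusted p = 0.0032 in limma, adjusted p = 0.514 with an estimated correlation). VSIG4, a complement receptor, had 49.7 ± 61.7 and 10.1 ± 13.8 FPKM, and the scavenger receptor CD163 91.7 ± 102 and 28.99 ± 11.5 FPKM. Of 8 endothelial markers 7 were higher (median 0.60, camera adjusted p = 0.0073 in limma, adjusted p = 0.514 with an estimated correlation), among them PLVAP at 3.13 ± 1.74 and 1.05 ± 0.864 FPKM and CDH5 at 3.80 ± 1.90 and 1.71 ± 1.17 FPKM. No member of these 4 lists passed, over all loci or adjusted over the list alone. A score averaging the B-cell, macrophage, fibroblast and endothelial lists was 0.35 ± 0.73 in PTCL (SD, n = 6) and -0.26 ± 0.35 in ALCL (SD, n = 8), exact permutation p = 0.0370, and it was 1.73 in PTCL 6. The difference of 0.60 became 0.33 without PTCL 6 (exact permutation p = 0.115). The exact permutation p also rose above 0.05, to at most 0.0793, without any 1 of ALCL 2, ALCL 3, ALCL 4, ALCL 5, ALCL 6 or PTCL 3. Without PTCL 6 none of the 4 lists was called, with medians of 0.73, 0.81, 0.49 and 0.36 and camera adjusted p of 0.141, 0.0689, 0.124 and 0.0689 in limma. Without ALCL 1 and ALCL 2 as well, the plasma-cell, macrophage and endothelial lists were called (camera adjusted p of 0.0085, 0.0120 and 0.0096 in limma) and the B-cell list was not (median 0.35, camera adjusted p = 0.494 in limma). The B-cell call was also lost without ALCL 7, PTCL 2 or PTCL 3 (medians 1.01, 0.64 and 0.53, camera adjusted p of 0.0711, 0.0994 and 0.204 in limma), and the plasma-cell call without ALCL 7 (median 0.73, camera adjusted p = 0.0941 in limma). The stricter filter of 5 FPKM (median 0.61, camera adjusted p = 0.185 in limma) and rescaling to TPM (median 1.51, where that of all loci was 0.58, camera adjusted p = 0.0518 in limma) ended the B-cell call too. With the stricter filter the endothelial list had too few members to be tested.

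All 16 tested JAK-STAT pathway genes, which carry cytokine signals, were higher in PTCL, with a median difference of 0.60 (camera adjusted p = 0.00023 in limma, adjusted p = 0.466 with an estimated correlation). PIM2, a kinase induced by cytokines, had 17.0 ± 19.2 FPKM in PTCL and 2.76 ± 1.10 FPKM in ALCL, and SOCS1, a feedback inhibitor, 3.85 ± 3.39 and 1.25 ± 1.10 FPKM. STAT3, named outside the rule for naming genes, had 76.0 ± 54.9 and 27.0 ± 19.7 FPKM. Of the 16 genes 5 had an unadjusted p under 0.05 and 0 passed, over all loci or adjusted over the list alone. All 9 immediate-early and stress genes were higher on the log2 scale (median 0.67, camera adjusted p = 0.0148 in limma, adjusted p = 0.514 with an estimated correlation). The mean FPKM of EGR2 was lower in PTCL, 18.1 against 21.5 in ALCL. JUN had 13.6 ± 9.99 and 5.63 ± 2.98 FPKM, and DUSP1 11.6 ± 17.2 and 3.21 ± 2.50 FPKM. Without PTCL 6 the JAK-STAT list was still called (median 0.57, camera adjusted p = 0.0063 in limma). The immediate-early list was not called without PTCL 6 (median 0.47, camera adjusted p = 0.212 in limma), nor without ALCL 1 and ALCL 2 as well (median 0.49, camera adjusted p = 0.0571 in limma). Its median was 1.01 without PTCL 4. With the non-T-cell score as a covariate neither list was called, at medians of 0.42 and 0.22, against 0.60 and 0.67 (camera adjusted p of 0.148 and 0.946 in limma).

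Cell-cycle, histone and ribosomal protein lists had medians below 0 in PTCL minus ALCL, on values as deposited. Of 19 cell-cycle genes 18 were lower on the log2 scale, with a median difference of -0.35 (camera adjusted p = 2.3e-05 in limma, adjusted p = 0.514 with an estimated correlation). No cell-cycle gene passed, over all loci or adjusted over the list alone. MKI67, a marker of dividing cells, had 234 ± 127 FPKM in PTCL and 346 ± 107 FPKM in ALCL, and the mitotic kinase BUB1 24.4 ± 9.79 and 39.1 ± 10.5 FPKM. Without PTCL 6 the median was -0.10 and the list was not called (camera adjusted p = 0.0889 in limma), while without ALCL 1 and ALCL 2 as well the median was -0.305 and the list was called (camera adjusted p = 0.00118 in limma). Of 11 histone genes 9 were lower (median -0.59, camera adjusted p = 2.3e-05 in limma, adjusted p = 0.514 with an estimated correlation), and HIST1H4C, at 88.8 ± 23.3 and 196 ± 80.8 FPKM, passed when adjusted over the list alone (adjusted p = 0.026 in limma) and not over all loci. HIST1H1B, a linker histone, had 61.9 ± 30.1 and 131 ± 89.4 FPKM. The list was drawn up as genes mostly without a poly(A) tail, which was not checked for each member. Which library protocol each sample received is not recorded. Of 12 ribosomal protein genes 10 were lower (median -0.15, camera adjusted p = 0.0165 in limma, adjusted p = 0.529 with an estimated correlation), with RPSA at 2907 ± 708 and 4397 ± 1310 FPKM and RPLP0 at 1048 ± 321 and 1412 ± 320 FPKM. The ribosomal call was lost after quantile normalization (camera adjusted p = 0.220 in limma), after rescaling to TPM (camera adjusted p = 0.167 in limma) and without any 1 of ALCL 3, ALCL 4, ALCL 7, PTCL 2 or PTCL 3 (medians -0.08, -0.06, -0.10, -0.07 and -0.07, camera adjusted p from 0.0541 to 0.144 in limma), and its median was -0.23 without ALCL 8 and -0.25 without PTCL 4. After rescaling to TPM the medians of these 3 lists were 0.23, 0.02 and 0.45, where the median of all loci was 0.58. With the non-T-cell score as a covariate 1 of the 9 calls was kept, that of the histone list, though 3 of the 9 lists are themselves part of that score. None of the 9 calls held with an estimated correlation, with fry, or in an exact permutation of list means after adjustment.

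**Figure D4:**
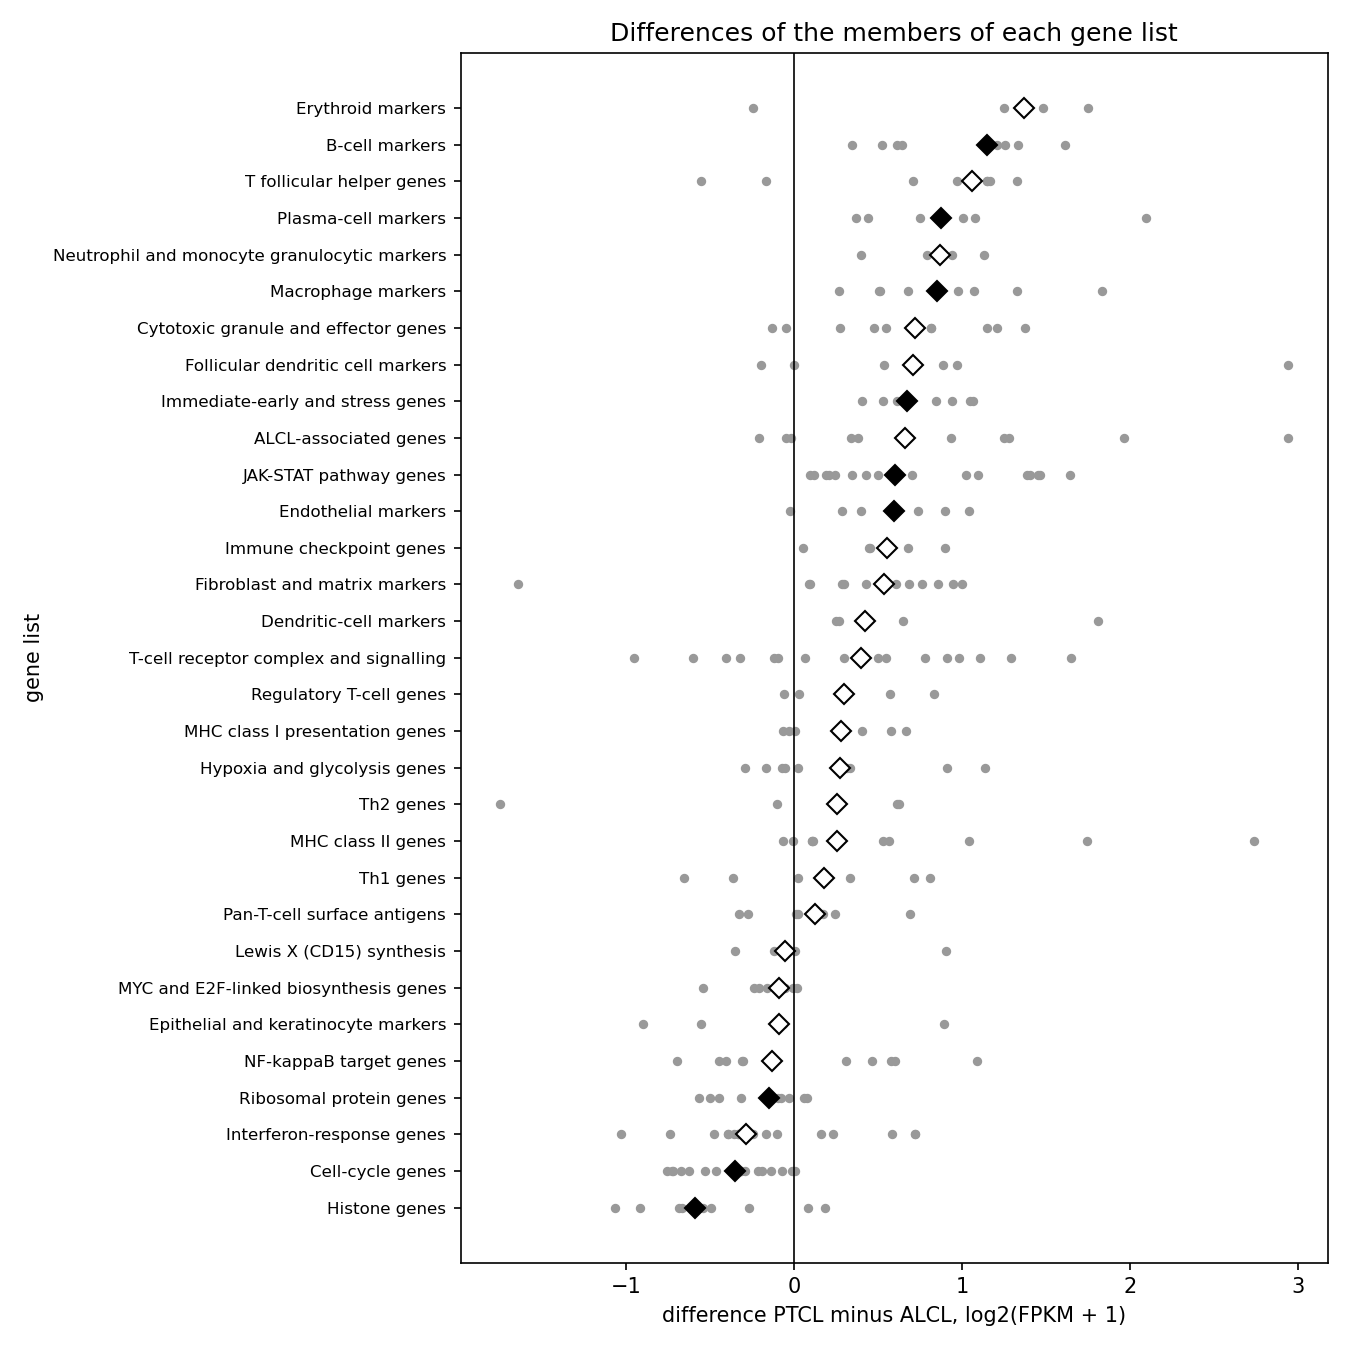
Grey points are the differences, PTCL minus ALCL on the log2(FPKM + 1) scale, of the tested members of 31 gene lists, and diamonds are list medians, filled where camera at a preset correlation gave an adjusted p under 0.05. The 9 filled diamonds run from -0.59 for histone genes to 1.15 for B-cell markers, on values as deposited; after rescaling to TPM the cell-cycle, histone and ribosomal medians lie above 0, and below the 0.58 of all loci.

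The remaining 22 tested lists were not called in the main fit of all samples. With all samples, the ALCL-associated list was called with the stricter filter, TPM and quantile normalization (camera adjusted p of 0.0336, 0.0390 and 0.0177 in limma). Cytotoxic and T follicular helper genes were called after quantile normalization (0.0364 and 0.0390). Dendritic, granulocytic, interferon, erythroid, fibroblast and MYC-linked lists were also called under some such setting. Without ALCL 1 and ALCL 2, 12 lists were called, the 9 and the cytotoxic, fibroblast and MYC-linked lists (camera adjusted p of 0.0091, 0.0253 and 0.0383 in limma), but with an estimated correlation none of the 12 was (adjusted p of 0.473, 0.574 and 0.494 for these 3). For 21 of the 22 lists, all but dendritic-cell markers, leaving out some 1 sample moved the median by over 1.5 times, so their directions are descriptive. The same held for 6 of the 9 called lists: B-cell, macrophage, endothelial, immediate-early, cell-cycle and ribosomal. Genes associated with ALCL had a median difference of 0.66 (camera adjusted p = 0.0567 in limma), with 1 of 10 members, CLU, passing when adjusted over the list alone, and IL2RA, an interleukin receptor, at 144 ± 188 FPKM in PTCL and 11.98 ± 12.03 FPKM in ALCL. Cytotoxic genes (0.72, and 0.47 without PTCL 6) included GZMH at 9.91 ± 8.46 and 3.11 ± 3.46 FPKM. T follicular helper genes (1.06, and 0.61 without PTCL 6) included MAF at 15.7 ± 14.9 and 5.34 ± 2.34 FPKM. T-cell receptor genes (0.40) included the kinase TXK at 9.68 ± 8.90 and 2.20 ± 1.89 FPKM, and pan-T-cell antigens (0.12) included CD7 at 4.16 ± 4.03 and 7.40 ± 18.8 FPKM, with medians of 3.06 and 0.586 FPKM and a difference on the log2 scale of 0.69. Th1, Th2 and regulatory T-cell lists had medians of 0.18, 0.26 and 0.30, with EOMES at 5.34 ± 3.5 and 2.66 ± 2.35, CCR8 at 43.9 ± 48.8 and 125 ± 90.4, and IL10 at 11.5 ± 18.0 and 4.45 ± 5.84 FPKM. The 4 measured genes of CD15 synthesis had a median of -0.05, with B4GALT1, a galactosyltransferase, at 41.3 ± 44.1 and 16.1 ± 8.23 FPKM. In the Th2 list the median was above 0 and the mean, -0.15, below it, and in the CD15 list the mean was 0.11. Without ALCL 1 and ALCL 2 the medians were 0.01 for T-cell receptor genes, -0.08 for pan-T-cell antigens and -0.38 for Th2 genes. Without ALCL 1 alone those of pan-T-cell antigens and Th2 genes were -0.07 and -0.28, and that of pan-T-cell antigens was -0.05 without PTCL 3 and -0.07 without PTCL 6. The CD15 median lay above 0, at most 0.11, without any 1 of ALCL 2, ALCL 3, ALCL 6, ALCL 8, PTCL 4 or PTCL 6, and at 0.48 after rescaling to TPM.

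Among other cell types, follicular dendritic (0.71), dendritic (0.43), granulocytic (0.87), fibroblast (0.54) and erythroid (1.37) markers had medians above 0 and epithelial markers (-0.09) below it. Without PTCL 6 the follicular dendritic median was 0.30, the granulocytic 0.62, the fibroblast -0.002 and the erythroid 0.82. Without PTCL 1 the granulocytic median was 0.39 and the epithelial 0.03. With the non-T-cell score as a covariate the follicular dendritic and dendritic medians were -0.33 and -0.11. CLEC10A, a dendritic-cell lectin at 12.8 ± 20.5 FPKM in PTCL and 1.41 ± 1.45 FPKM in ALCL, passed when adjusted over its list alone (adjusted p = 0.048 in limma), as did CLU among follicular dendritic markers. FCN1 had 5.21 ± 3.69 and 2.73 ± 2.36, PDGFRB 7.47 ± 5.19 and 4.03 ± 1.48, HBA1 25.5 ± 28.7 and 9.60 ± 18.0, and KRT18 2.88 ± 1.99 and 1.02 ± 0.812 FPKM. MHC class II (0.25) and class I (0.28) lists included HLA-DRB1 at 123 ± 204 and 2.62 ± 2.82 FPKM and TAPBP at 46.9 ± 10.2 and 32.4 ± 11.7 FPKM; the copies of HLA-DRB genes are similar and vary between people, which leaves the first uncertain, and the class II median was -0.03 without ALCL 1 and -0.03 without ALCL 7. Immune checkpoint (0.56) and hypoxia (0.27) lists included CD274, encoding PD-L1, at 12.2 ± 16.7 and 3.96 ± 3.89 FPKM and VEGFA at 18.5 ± 11.6 and 9.30 ± 6.39 FPKM. Without PTCL 6 these 2 medians were 0.21 and 0.09, the checkpoint median was -0.05 without ALCL 1 and ALCL 2 as well, and the hypoxia median was -0.03 without ALCL 1 and ALCL 2 and -0.10 with sample weights. Interferon-response (-0.29), NF-kappaB (-0.13) and MYC-linked (-0.09) lists included IFI44L at 4.30 ± 4.33 and 9.47 ± 6.09, NFKB1 at 21.3 ± 6.25 and 29.3 ± 7.165, and ODC1 at 67.6 ± 39.1 and 83.8 ± 22.6 FPKM. After rescaling to TPM the medians of these 3 lists and of epithelial markers lay above 0, at 0.14, 0.48, 0.48 and 0.16, and below that of all loci. Of the 22 lists 11 were called by camera when some 1 sample was left out, at adjusted p from 0.0034 to 0.0477 in limma. T follicular helper genes were called without ALCL 1, 5, 7 or 8 or PTCL 1, 2, 4 or 5, granulocytic markers without ALCL 1, 5 or 6 or PTCL 2, 3 or 5, and interferon-response genes without ALCL 2, 3 or 4 or PTCL 1, 2 or 3. The ALCL-associated list was called without ALCL 1 or PTCL 2, 3 or 4, cytotoxic genes without ALCL 1 or 5 or PTCL 2 or 5, and dendritic-cell markers without PTCL 1, 4 or 5. Erythroid markers were called without ALCL 4 or PTCL 2 or 4, MYC-linked genes without ALCL 2 or PTCL 1 or 5, fibroblast markers without PTCL 1, and follicular dendritic markers and T-cell receptor genes without PTCL 5. The Th17, eosinophil and mast-cell, NK-cell, adipocyte and muscle, and mitochondrial lists had fewer than 3 tested members and were not tested.

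No separation of whole profiles by group was detected. Mean distance, 1 minus Pearson r, was 0.184 between groups, 0.151 within PTCL and 0.206 within ALCL. Distance between groups minus distance within groups was -0.0032 (one-sided exact permutation p = 0.547), and distance within PTCL minus that within ALCL was -0.056 (exact permutation p = 0.478). Without ALCL 1 and ALCL 2 these differences were 0.0096 (one-sided exact permutation p = 0.0584) and 0.040 (exact permutation p = 0.258). The most similar sample belonged to the same group for 3 of 6 PTCL and 6 of 8 ALCL, 9 in all, where random splits gave 6.62 on average (one-sided exact permutation p = 0.189). ALCL 4 and ALCL 6 correlated at 0.950, the highest pair. The first principal component held 27.4% of the variance (exact permutation p = 0.260 between groups).

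**Figure D5:**
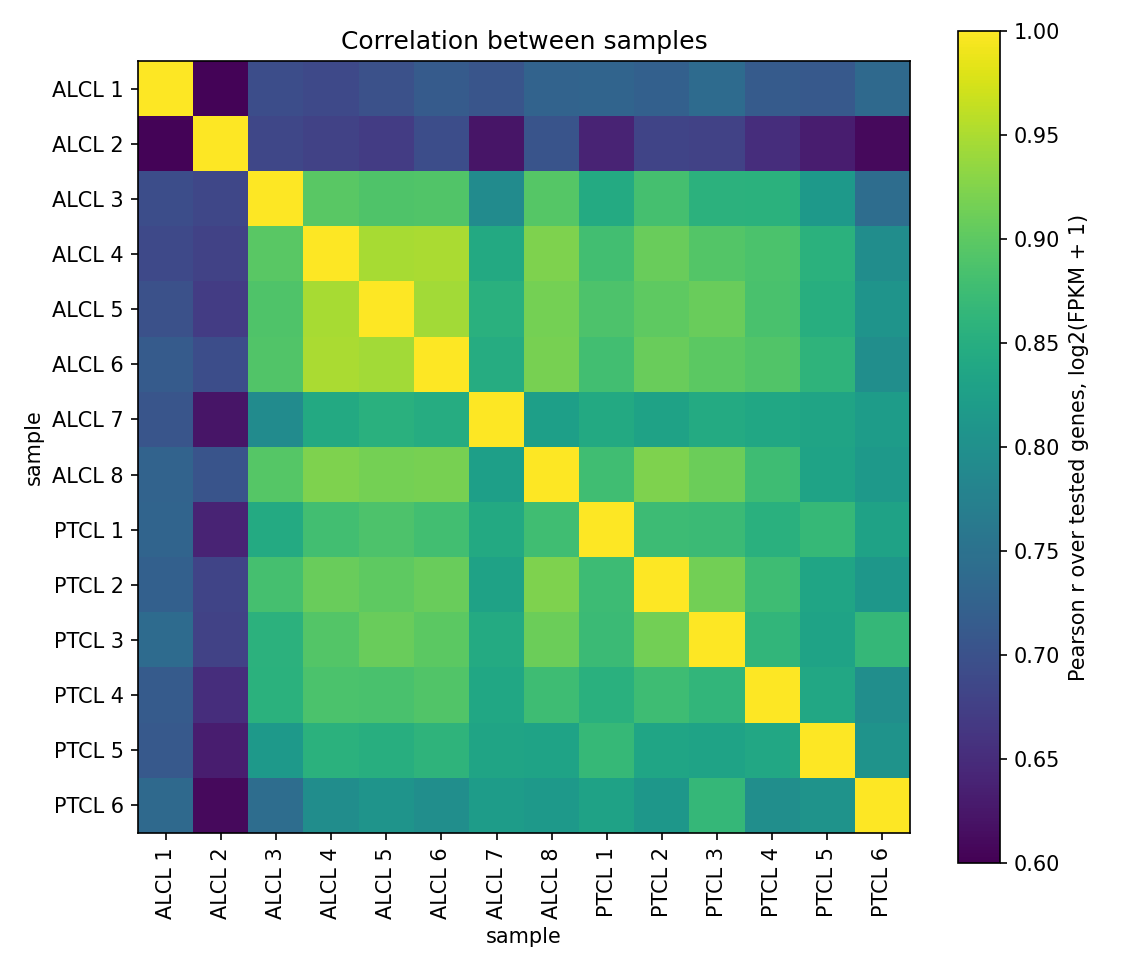
Colours give Pearson r over the 11248 tested loci for each pair of the 14 samples, on log2(FPKM + 1). ALCL 1 and ALCL 2 have mean r of 0.707 and 0.658 with the other samples, and the remaining samples lie between 0.788 and 0.861.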

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

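The tests without ALCL 1 and ALCL 2 were chosen after the results were seen, while the tests with a covariate and the counts over other splits were planned. In 118 sets of values, each 1 group's samples for 1 gene, list or library measure, 9 had a sample far from the rest of its group by Dixon's ratio, where chance would give about 6. PTCL 6 accounts for 4 of them. Its mean log2 value was 3.48 for cell-cycle genes, with the next PTCL at 5.06, and 5.51 for erythroid markers, 5.42 for immediate-early genes and 2.62 for TMOD1. ALCL 7 was low in BATF3, at 0.395, and in the 3-gene score, at 1.37. ALCL 8 was high in PAX5, at 3.49. ASB2 was low in ALCL 1, at 0.697, and high in PTCL 3, at 2.53.

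For the lower cell-cycle and histone levels in PTCL, the values of the 2 shallow libraries argue against them as the source. ALCL 1 and ALCL 2 had mean log2 values of 4.84 and 4.46 for cell-cycle genes, below the ALCL mean of 5.27. For histone genes they had 7.29 and 6.26, below the ALCL mean of 7.91. Leaving out such low values nearly fixes the direction. The medians without them, -0.57 for the cell-cycle list and -0.89 for the histone list, farther from 0 than with all samples, are therefore no separate test. For the cell-cycle list, a larger share of non-T cells in PTCL remains a candidate explanation: with the non-T-cell score as a covariate the difference of the list mean was 0.0232 (SE 0.324), from -0.37 (SE 0.33) without it, with errors nearly as large as the shift. PTCL 6 has the highest non-T-cell score, 1.73, and the lowest cell-cycle value, and it was singled out after its values were seen, so neither the median of -0.10 without it nor that of -0.305 without it and the 2 shallow libraries, called by camera (adjusted p = 0.00118 in limma), can separate the explanations; that score itself differed by 0.33 without PTCL 6, from 0.60. For the histone list neither non-T cells nor fewer cycling cells could be told from a difference of its own, with -0.42 (SE 0.49) and -0.15 (SE 0.29) after each covariate, and a difference between the 2 lymphoma types stays open and untested. Some of its genes may lack a poly(A) tail, which was not checked for each member, so a difference in library protocol also stays open. Without a record per sample that difference could not be tested.

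Chance could not be excluded for the count of genes with an unadjusted p under 0.05 or for the count of called lists. In 37 of 100 splits of the 14 samples into 6 and 8, the real one included, at least as many genes as the real 535 had an unadjusted p under 0.05, with 1106 the highest of the other splits. At least as many lists as the real 9 were called by camera in 18 of the 100 splits, with 17 the highest of the others. For genes past the adjusted threshold the comparison decides nothing: the real count was 0, which all 100 splits reach, and the highest of the others was 1.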

How the results depend on the processing

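The 12-sample, 11-sample, joint-locus and list-mean fits, and leaving samples out of the non-T-cell score and the ratio of HAND1 to NSMCE2, were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the labels give no shared replicate numbers. The count of genes passing, 0, became 9 with sample weights and 2 with 12 samples, and ran from 0 to 1 when single samples were left out (ASB2 without ALCL 1; without 1 other sample, a locus of an excluded kind, not reported here). Genes with an unadjusted p under 0.05 numbered 1644 with sample weights, 925 with 12 samples, 847 under TPM, 363 with the covariate and 301 with the stricter filter, against 535. The share higher in PTCL was 53.2% with the stricter filter, 54.8% with weights and 53.0% with 12 samples. The count of called lists, 9, became 14 without a filter, 3 with the covariate (histone genes, the 1 kept of the 9, with interferon genes newly called lower, and fibroblast genes too, though their list is part of that score), 0 with an estimated correlation, 0 with fry and 0 with exact list means, and ran from 3 without PTCL 6 to 16 without PTCL 5, with 14 without PTCL 1. TPM moved the median of all loci from 0.10 to 0.58, and all 8 list medians below 0 crossed it, none past 0.58. They became 0.23 for cell-cycle, 0.14 for interferon, 0.0215 for histone, 0.45 for ribosomal, 0.16 for epithelial and 0.48 each for CD15, NF-kappaB and MYC-linked genes, and TNFRSF8 was 0.37 and the FUT4 locus 0.0539. With the covariate, fibroblast and endothelial medians, both part of that score, and the cell-cycle median were -0.58, -0.0130 and 0.0518, and TNFRSF8 was 0.21. Uncalled medians that changed sign with it were those of T-cell receptor genes (-0.13), pan-T-cell antigens (-0.29), follicular dendritic (-0.33) and dendritic (-0.11) markers, and checkpoint genes (-0.30). Those of CD15 (0.26) and MYC-linked (0.09) genes did so too. Left-out samples moved TNFRSF8 from -0.59 to 0.23 (without PTCL 4), the 3-gene difference from -0.43 to 0.27 and the separation of distances from -0.0147 to 0.00769. The 3-gene difference was -0.00166 after quantile normalization and -0.0796 with 12 samples. The separation was 0.0096 with 12 samples, 0.0066 with 11 and 0.00772 over the 1000 most variable genes, and the within-group difference was 0.040 with 12 and 0.026 with 11. Rescaling to TPM divides by the FPKM sums, 1068430 in ALCL 1 and 4499090 in ALCL 2, against 369166 to 589983 in the other samples. It therefore lowers all loci of these 2 ALCL libraries relative to every other sample. The cause of the other changes was not tested, apart from fewer samples or loci. Of 2198 values of named genes, 9 passed under an alternative and 67 uncalled ones changed sign. The low estimated depth of ALCL 1 and ALCL 2 would limit low genes most.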

Other observations

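All tests in this part except the fit with sample weights were chosen after the values were seen. NSMCE2 was high in ALCL once the 2 shallow libraries were left out, and HAND1 was listed at 0 in every PTCL. A gain of the chromosome 8 region would raise the neighbouring genes, and the larger of their ratios of medians, ALCL over PTCL, was 1.11 (KIAA0196), with 1.05 for TRIB1 and 16.6 for NSMCE2, which argues against a gain that spans both neighbours. RNA of a single source spread over several ALCL libraries would keep HAND1 and NSMCE2 in a fixed ratio, but the largest ratio was 9.89 times the smallest over 6 ALCL, and 5.46 times without the shallow ALCL 2. Expression of both genes in part of the ALCL samples may be worth a further look, as a hypothesis found in these same samples. Both passed with sample weights (adjusted p = 0.00998 for HAND1 and 0.00195 for NSMCE2 in limma) and neither in the unweighted fit of all 14. The weights were estimated from these same values, so the weighted fit is no separate support. It gave 1644 genes with an unadjusted p under 0.05, against 535 without weights, and other splits of the samples were not run with weights.

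Some values in the shallow libraries exceed what a library can hold, if FPKM was scaled by each library's own mapped fragments. In ALCL 2, F5 was listed at 1825970 FPKM, which over its longest annotated transcript of 7039 nt comes to 12853000 fragments in 1000000. Such values exceeded 1000000 in 1000000 at 2 loci in ALCL 1 and 4 in ALCL 2, and at 0 loci in the other samples. High single loci below that cut occurred elsewhere too. CKMT1A in ALCL 3 and TMPRSS3 in PTCL 4 came to 129020 and 141499 fragments in 1000000, and whether these have the same source was not tested. A candidate explanation is an effective length set far below the transcript length. The FPKM of F5 requires it only if the gene is the source and FPKM was scaled by the library's own mapped fragments. The scaling between samples is not given, so the size of these values cannot decide it. In ALCL 1 and ALCL 2 the highest loci held most of the FPKM sum that rescaling to TPM divides by, and no biological explanation was tested.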
